A study of Homo sapiens with 8 samples.

How the data were processed

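RNA-seq libraries of the human colon cancer line SW620 were grouped from the sample titles into empty-vector cells with DMSO, empty-vector cells with 10 nM estradiol, empty-vector cells with 1 µM G1, and ERβ-transduced cells with 100 nM ICI, each with 2 libraries, at 24 h. Libraries were made with a stranded mRNA kit, per the labels. ERβ-transduced cells without ICI were not analysed here, so the transduction and the compound changed together. The deposited count table holds whole-number read counts per gene for 63677 genes, which were not normalized. The deposited FPKM table holds 63655 genes, normalized by the authors to gene length and sequencing depth. The submitters' processing notes name TopHat2 2.0.4, Picard 1.29, HTSeq 0.6.1, Cufflinks 2.1.1, SAMtools and the GRCh37 build, with no role or order, and the strand setting of the counting is not given in the sources used here. Totals ran from 29415611 to 40911457 counts per library, so that 3 counts, the limit set by a count of 0, correspond to 0.0733 to 0.102 CPM.

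Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr by group, estimateDisp, glmQLFit and glmQLFTest at default settings, 1 coefficient per group over all 8 libraries). The filter left 18495 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, with no fold minimum. Because each group has 2 libraries, all groups shared an estimate of the spread with 4 residual degrees of freedom, and a biological coefficient of variation of 0.211 was estimated. The comparisons were estradiol, G1, and ERβ plus ICI against vehicle, and estradiol against G1. Gene lists were tested with camera of limma 3.58.1 on voom values, two-sided, with a preset inter-gene correlation of 0.01 and adjustment over the 22 lists of each comparison. Intervals of ratios of counts are exact 95% intervals. CPM are counts scaled to the library's total over the tested genes times its TMM factor (0.93 to 1.05), while ratios of counts, limits set by 3 counts and the alternative filter of 1 CPM use the totals over all genes alone.

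The 22 lists were estrogen receptor, aryl hydrocarbon receptor, YAP/TEAD, Wnt, p53 and TGF-β target genes, immediate early and MAPK feedback genes, NF-κB genes, interferon-stimulated genes, G1/S genes, G2/M genes, tubulin genes, integrated stress response genes, endoplasmic reticulum chaperones, cholesterol synthesis genes, hypoxia and glycolysis genes, epithelial-mesenchymal transition genes, colon differentiation genes, core clock genes, ribosomal protein genes, mitochondrially encoded genes, and markers of fibroblasts, endothelium and immune cells. Groups, tests, lists, the rule for named genes and a set of alternatives were fixed before the data were examined. Under that rule the text gives ESR1, ESR2 and GPER1 in every library. It names up to 12 genes per direction and comparison with the largest log2 fold change among called genes of at least 1 CPM in either group whose libraries did not overlap, leaving out clone-style names. From each list it names up to 4 called members with the smallest p, or else up to 2 members as values. Genes called in the same direction against vehicle in more than 1 comparison were to be named too, and there were none. Some genes that the rule takes are not reported here.

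Alternatives fixed beforehand were RLE and upper-quartile scaling, no filter, a filter of 1 CPM in 2 libraries, a fold minimum of 1.5, the libraries of the compared groups alone, the mean of the empty-vector groups as control, limma-voom, DESeq2 1.42.0, limma on log2(FPKM + 1) with FPKM of at least 0.5 in 2 libraries or without a filter, and on log2(FPKM + 0.1), fry and an estimated correlation for lists, the replicate number as a block, and leaving out each replicate of the groups compared. Chosen after the data were seen were GC and length offsets, the 6 empty-vector libraries alone, both together, the block and the leave-one-out fits with these offsets, and leaving out replicates of groups not compared. For the offsets, the log2 CPM deviation of each library from the mean was fitted as a smooth function of GC content and log2 length (mgcv 1.9.3, basis size 8) and added to the TMM offsets of the edgeR fit. GC content and length came from a GRCh38 annotation, matched on gene identifiers, for 18045 of the tested genes (97.6%). Symbols were taken from a reference table by gene identifier for 52181 identifiers, and from the deposited tables for the 11496 without a reference name.

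The pipeline was tested on simulated data with the real means and library sizes, 18495 genes and 100 genes changed at each fold size. With no GC trend, edgeR recovered 85% of genes changed by 2 log2 units and 14% of those changed by 1 between ERβ plus ICI and vehicle, with 9 unchanged genes called. For estradiol against vehicle these were 87%, 10% and 6 genes, for G1 against vehicle 83%, 12% and 7, and for estradiol against G1 85%, 15% and 5. With the smooth trends fitted to the real libraries added, 10234 unchanged genes were called between ERβ plus ICI and vehicle without offsets. With offsets 9 were called, and 95% and 66% of changed genes were recovered, against 87% and 58% without them. Data with the trend were drawn with the spread of the offset fit, and those without it with that of the plain fit. Recovery is therefore not comparable between the simulations with and without the trend. The added trends had the form that the offsets fit, so this does not test how well the offsets remove the real trends. Overlaps between comparisons that share vehicle libraries were set beside 40 simulations of unchanged groups, in which the vehicle libraries were simulated too, without a GC trend. Replicate libraries differed by more than sampling noise in every group, so none was taken as a duplicate.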

Results

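Polyadenylated RNA was sequenced from SW620, an established cell line from a lymph node metastasis of a colorectal adenocarcinoma, to profile estrogen signalling. The 8 libraries fell into 4 groups of 2. Cells transduced with an empty vector received the DMSO vehicle, 10 nM estradiol or 1 µM G1, an agonist of the membrane estrogen receptor GPER1, and cells transduced with estrogen receptor β (ERβ) received 100 nM of a compound the labels call ICI. All were harvested after 24 h. Library totals ran from 29415611 to 40911457 gene counts. Expression is given as CPM (counts scaled to the TMM-adjusted library total), mean ± SD of n = 2 libraries. Changes are given as log2 fold changes ± SE, with Benjamini-Hochberg adjusted p-values from edgeR. The SE is not an output of edgeR. It was derived as the size of the log2 fold change divided by the square root of the F statistic, and is approximate. Nothing in the labels says that the libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

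The estrogen receptors differed widely in level. ESR1, which encodes ERα, had at most 1 count in any library, below the limit of 3 counts that a count of 0 allows (0.0733 to 0.102 CPM of the unadjusted library totals). ESR2, which encodes ERβ, had 315 and 278 counts in the ERβ-transduced libraries (9.40 and 7.72 CPM). Among empty-vector libraries it had 0 and 1 counts with vehicle, 5 and 8 with estradiol and 3 and 5 with G1. Scaled by unadjusted library totals, the ratio of ERβ-transduced to all empty-vector libraries was 80.9 (exact 95% interval 53 to 130, counting error only, as for all such intervals and floors here). Against vehicle alone, with 1 count, it was 527 (94.1 to 20800). GPER1 was expressed throughout, at 5.81 and 14.6 CPM with vehicle, 28.8 and 30.4 with estradiol, 15.3 and 20.2 with G1 and 22.0 and 17.1 in the ERβ plus ICI libraries.

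The libraries also differed in how expression depended on the GC content of the gene. Across genes, which are not independent replicates, the deviation of a library from the mean of all 8 correlated with GC content at r = -0.80 and -0.53 for the vehicle libraries and at 0.71 and 0.57 for the ERβ plus ICI libraries. Estradiol libraries lay between them (-0.15 and -0.11), as did G1 libraries (-0.47 and -0.30). Within groups, the vehicle libraries differed from each other by 0.52 log2 units per 10 percentage points of GC, and the ERβ plus ICI libraries by 0.52. The trend was small between the estradiol libraries (0.016) and between the G1 libraries (0.089). GC content is therefore given beside the gene groups below, with GC-adjusted values from a second fit. In it smooth GC and length trends of each library entered as offsets, a choice made after the data were seen. The sign of the correlation followed the groups, positive with ERβ plus ICI and negative in all empty-vector libraries. The offsets were fitted to each library's whole deviation, so they also remove any response to treatment that follows GC content. A GC-adjusted value is therefore a second reading, which may be adjusted too far, and not a corrected one. GC-adjusted p-values of lists are from camera at the preset correlation only. An estimated correlation and fry were run only without the offsets, so a GC-adjusted p does not answer a list's loss with an estimated correlation.

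**Figure D1:**
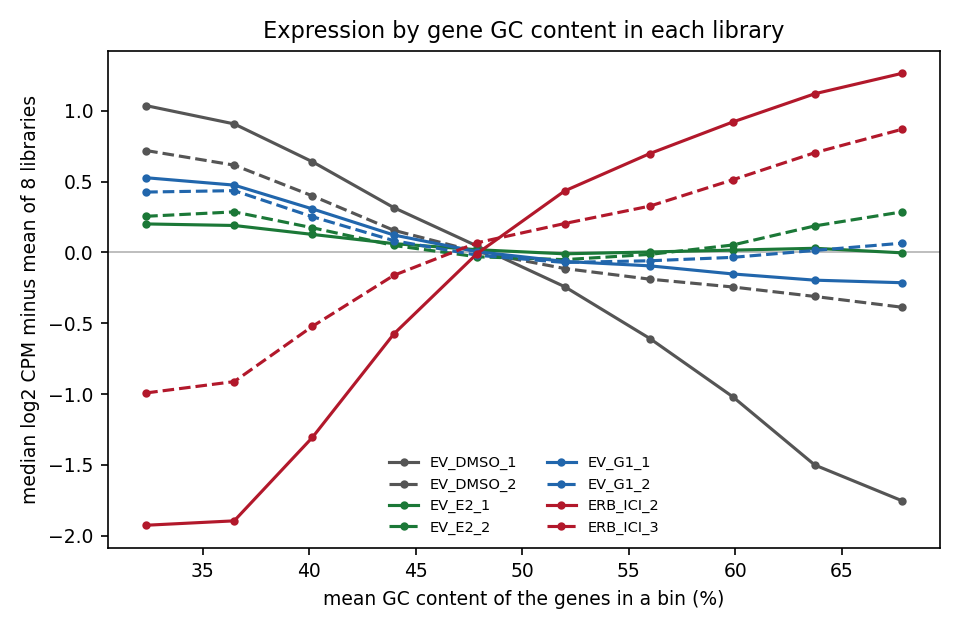
Median log2 CPM of the genes in each bin of GC content (x axis, %), as the difference from the mean of the 8 libraries (y axis), with 1 line per library, coloured by group, and the libraries of a group drawn solid and dashed (EV, empty vector; ERB, ERβ; E2, estradiol). In genes with a mean GC content of 36.5%, the medians ran from -1.90 in an ERβ plus ICI library to 0.91 in a vehicle library, and in genes of 63.7% from -1.50 in a vehicle library to 1.12 in an ERβ plus ICI library.

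The comparison of ERβ plus ICI with vehicle covers the joint effect of the transduction and the compound, which were never applied apart in these libraries. Genes of the integrated stress response rose together. TRIB3, a pseudokinase induced by the transcription factor ATF4, went from 34 ± 6.92 to 2329 ± 736 CPM (log2 fold change 6.10 ± 0.30, adjusted p = 2.91e-05; GC-adjusted 4.45 ± 0.18). Asparagine synthetase (ASNS) went from 55.8 ± 5.58 to 902 ± 122 CPM (4.02 ± 0.21, adjusted p = 2.91e-05). CHAC1, a glutathione-degrading enzyme, rose by 6.11 ± 0.33 (GC-adjusted 4.32 ± 0.15) and SESN2, a stress-induced inhibitor of mTORC1 signalling, by 5.96 ± 0.35 (GC-adjusted 4.64 ± 0.15). Of the 16 measured members of this list 15 were called higher and none lower, with a median log2 fold change of 2.85, and the list passed the set test (camera, adjusted p = 8.75e-09; adjusted p = 0.0565 with an estimated correlation). Its members have a median GC content of 54.5% against 48.1% for all genes tested, and with GC adjustment all 16 were called higher with a median of 2.48.

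Among the largest rises, INHBE, an inhibin β subunit, went from 0.86 ± 0.12 to 218 ± 50.9 CPM (7.98 ± 0.32; GC-adjusted 7.16 ± 0.14), and ADM2, encoding adrenomedullin 2, from 0.41 ± 0.21 to 118 ± 27.5 CPM (8.12 ± 0.41; GC-adjusted 6.55 ± 0.15). The metabolic hormone gene FGF21 had no count with vehicle and 164 counts with ERβ plus ICI, at least 48.5-fold higher against a floor of 3 counts over the group. On the same basis the trypsin inhibitor gene SPINK1 was at least 61.0-fold higher, KLHDC7B at least 77.5-fold, BEX1 at least 53-fold, the tachykinin gene TAC4 at least 36.7-fold, the methionine adenosyltransferase gene MAT1A at least 23.7-fold, and OSCAR, an immune receptor gene, at least 22.8-fold. TREML2 had 254 counts against 1 (ratio 226, exact 95% interval 40.1 to 8940). TONSL-AS1 was at least 28.1-fold higher, but is antisense to another gene, and whether the counting used strand is not stated. Among p53 target genes GDF15, a stress-induced cytokine, rose by 4.15 ± 0.46 (GC-adjusted 2.34 ± 0.13), the BH3-only gene BBC3 by 5.62 ± 0.67 (GC-adjusted 3.6 ± 0.48) and the death receptor gene TNFRSF10B by 1.77 ± 0.18, and 9 of 18 members of that list rose while 6 fell (camera adjusted p = 0.650).

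Cell-division genes fell. CENPE, a kinetochore motor, went from 77.6 ± 13.2 to 0.56 ± 0.54 CPM (-7.08 ± 0.61, adjusted p = 1.62e-04; GC-adjusted -4.45 ± 0.28), the mitotic kinesin gene KIF20B from 264 ± 46.5 to 2.65 ± 2.61 (-6.63 ± 0.69; GC-adjusted -4.01 ± 0.30) and the spindle gene ASPM from 269 ± 44.9 to 2.96 ± 2.88 (-6.50 ± 0.70; GC-adjusted -4.12 ± 0.31). The topoisomerase gene TOP2A changed by -4.71 ± 0.38 (GC-adjusted -2.89 ± 0.11), the hyaluronan-binding spindle gene HMMR by -5.05 ± 0.44 (GC-adjusted -2.99 ± 0.17) and KIF20A by -2.34 ± 0.19. The centromere genes CENPF and SGO2 changed by -5.90 ± 0.62 and -6.38 ± 0.44 (GC-adjusted -4.31 ± 0.31 and -3.91 ± 0.23), FAM111B by -6.32 ± 0.33 (GC-adjusted -4.30 ± 0.17), and the centrosomal genes CCDC18 and LRRCC1 by -5.90 ± 0.55 and -5.86 ± 0.38 (GC-adjusted -4.06 ± 0.27 and -3.29 ± 0.19). Of 22 measured G2/M genes 18 fell and none rose, with a median of -2.62 (camera adjusted p = 1.06e-07; adjusted p = 0.283 with an estimated correlation). This list has a median GC content of 43.2%, and GC adjustment brought its median to -1.86 with 21 members called lower. Of 20 G1/S genes 13 fell and 1 rose (camera adjusted p = 7.78e-04; adjusted p = 0.251 with an estimated correlation). They included cyclin E2 (CCNE2, -4.81 ± 0.37; GC-adjusted -2.75 ± 0.13), thymidylate synthase (TYMS, -1.85 ± 0.18; GC-adjusted -2.24 ± 0.09) and the ribonucleotide reductase genes RRM1 (-2.68 ± 0.27; GC-adjusted -2.04 ± 0.12) and RRM2 (-1.72 ± 0.18), and after GC adjustment 19 were lower.

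Some sterol genes and genes of the colon epithelium were called singly, in lists that did not pass the set test. INSIG1, a sterol-feedback regulator, fell by 3.06 on the log2 scale (SE 0.26; GC-adjusted -2.83 ± 0.15), and STARD4, IDI1 and SQLE changed by -3.98 ± 0.30, -2.86 ± 0.33 and -1.52 ± 0.21. For STARD4, with a GC content of 34.2%, the adjusted value was -1.37 ± 0.12, and for IDI1 it was -1.67 ± 0.11. The 21 cholesterol synthesis genes held 10 lower and 4 higher calls (camera adjusted p = 0.160, and 0.00223 with GC adjustment, both at the preset correlation). With an estimated correlation, used only without offsets, the camera adjusted p was 0.522. E-cadherin (CDH1) went from 24.3 ± 1.72 to 64.2 ± 1.61 CPM (1.40 ± 0.20, adjusted p = 6.45e-04; GC-adjusted 1.47 ± 0.09) and the tight-junction gene CLDN7 from 0.52 ± 0.40 to 24.0 ± 5.69 CPM (5.51 ± 0.49; GC-adjusted 4.08 ± 0.28). The mesenchymal genes ZEB1 and VIM changed by -3.90 ± 0.47 (GC-adjusted -1.93 ± 0.20) and -1.28 ± 0.17. The epithelial-mesenchymal list mixes genes of both states, and 6 of its 12 members rose and 5 fell. The intestinal transcription factor gene CDX2 rose by 2.33 ± 0.27 (GC-adjusted 1.42 ± 0.16), the mucosal peptide gene TFF3 by 2.07 ± 0.40 (GC-adjusted 1.14 ± 0.25) and keratin 8 (KRT8) by 1.34 ± 0.25 (GC-adjusted 0.36 ± 0.11), while the fatty acid binding protein gene FABP1 changed by -2.22 ± 0.34, with 7 of 11 colon differentiation genes higher and 2 lower (camera adjusted p = 0.104).

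The stem-cell gene LGR5 fell by 2.45 (SE 0.30; GC-adjusted -1.75 ± 0.13) and the transcription factor gene PROX1 by 3.21 (SE 0.32; GC-adjusted -1.58 ± 0.09), whereas MYC rose by 1.62 ± 0.18 (GC-adjusted 0.82 ± 0.14), among 5 higher and 5 lower calls in 18 Wnt target genes. That list, with a median GC content of 53.7%, had a camera adjusted p of 0.948, and 0.0356 with a downward direction after GC adjustment, both at the preset correlation. With its estimated correlation of 0.367, used only without offsets, the camera adjusted p was 0.976. Of 15 classical estrogen receptor target genes 4 rose, led by STC2 (2.73 ± 0.21) and the unfolded protein response factor gene XBP1 (2.41 ± 0.20; GC-adjusted 3.52 ± 0.29), and 4 fell, led by the proto-oncogene MYB (-3.06 ± 0.29; GC-adjusted -2.45 ± 0.13) and RBBP8 (-2.92 ± 0.34; GC-adjusted -1.50 ± 0.12), with a camera adjusted p of 0.948. After GC adjustment 4 were higher and 8 lower, with a median of -0.79 against -0.30 before and an adjusted p of 0.172. Ribosomal protein genes rose as a list, 14 of 20 higher and 2 lower (camera adjusted p = 7.78e-04; adjusted p = 0.283 with an estimated correlation; GC-adjusted p = 3.75e-04), including RPS12 (1.43 ± 0.18) and RPLP0 (1.44 ± 0.22). These families have many pseudogenes, so their counts are uncertain. Of 20 immediate early and MAPK feedback genes 12 rose and 2 fell (camera adjusted p = 0.0239; adjusted p = 0.522 with an estimated correlation; GC-adjusted p = 0.144). They included the stress-induced factor gene ATF3 (4.99 ± 0.29), the phosphatase gene DUSP1 (2.1 ± 0.29; GC-adjusted 1.11 ± 0.17) and IER2 (2.39 ± 0.36; GC-adjusted 0.79 ± 0.10).

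The remaining lists had members going both ways and were not called from the counts as deposited. With GC adjustment tubulin genes were called lower (adjusted p = 0.0193, 3 of 11 members above vehicle, and 0.0544 without ERβ plus ICI replicate 3) and mitochondrially encoded genes higher (adjusted p = 0.028, 12 of 13 above vehicle). Both calls used the preset correlation. Without offsets, camera with estimated correlations (0.69 for tubulin and 0.185 for mitochondrially encoded genes) gave an adjusted p of 0.976 for each list. Of 16 endoplasmic reticulum chaperone genes 6 rose and 1 fell (camera adjusted p = 0.767), with HERPUD1 at 2.18 ± 0.22 and HSP90B1 at -1.94 ± 0.27 (GC-adjusted -0.80 ± 0.10). Hypoxia and glycolysis genes gave 5 higher and 4 lower calls in 17 (camera adjusted p = 0.815), among them VEGFA at 2.97 ± 0.23 and LDHA at -1.26 ± 0.17. Interferon-stimulated genes gave 4 and 7 in 17 (0.767), with IRF7 at 3.89 ± 0.54 (GC-adjusted 1.90 ± 0.22). NF-κB genes gave 5 and 2 in 15 (0.332), with IRF1 at 2.0 ± 0.25 and BIRC3 at -3.85 ± 0.30 (GC-adjusted -1.29 ± 0.28). YAP/TEAD targets gave 3 and 4 in 12 (0.948), with AMOTL2 at 2.62 ± 0.23 (GC-adjusted 1.75 ± 0.13) and AJUBA at 2.04 ± 0.21, and TGF-β targets 5 and 3 in 13 (0.948). Core clock genes gave 7 and 5 in 15 (0.767), aryl hydrocarbon receptor targets 4 and 2 in 7 (0.370), tubulin genes 3 and 2 in 11 (0.701), and mitochondrially encoded genes 2 and 1 in 13 (0.767). Markers of fibroblasts, endothelium and immune cells gave 2 higher and 2 lower calls in 8 (0.948). The proteoglycan gene LUM, at 42.6 ± 8.12 CPM with vehicle, was at 1.10 ± 0.92 CPM with ERβ plus ICI (-5.26 ± 0.51; GC-adjusted -3.17 ± 0.20), and PDGFRB rose by 1.58 ± 0.32 (GC-adjusted 0.73 ± 0.21). Counts adjusted over the list alone were the same as those given here for all 22 lists, except interferon-stimulated genes (4 higher, 8 lower), endoplasmic reticulum chaperones (5 and 1), epithelial-mesenchymal genes (6 and 6), colon differentiation genes (8 and 2) and mitochondrially encoded genes (1 and 1).

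**Figure D2:**
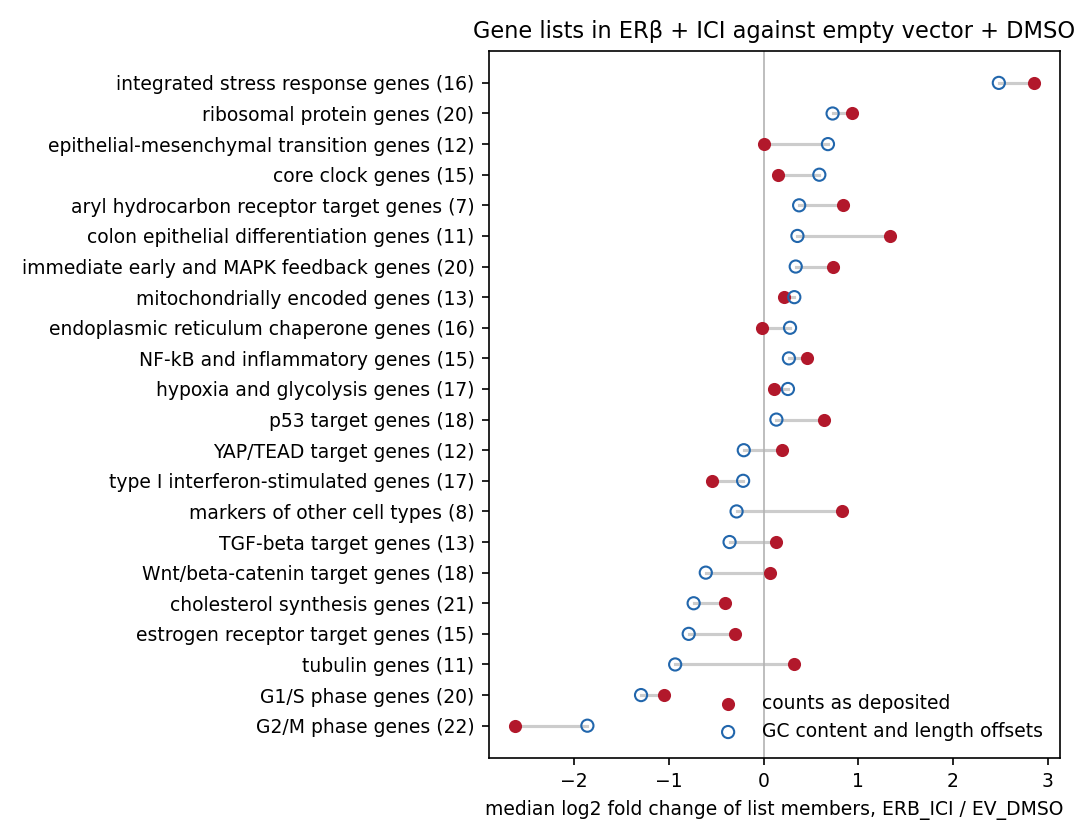
Median log2 fold change of the measured members of each gene list (x axis) between ERβ plus ICI and vehicle, with the number of measured members beside each name; filled points are from the counts as deposited and open points from the GC-adjusted fit. Integrated stress response genes lie at 2.85 and 2.48, and G2/M genes at -2.62 and -1.86.

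In all, 11656 of 18495 genes were called between ERβ plus ICI and vehicle, 5892 higher and 5764 lower. The calls followed GC content: among 4512 genes of 23.5 to 42.2% GC, 3346 were lower and 141 higher, and among 4511 genes of 55.7 to 74.5% GC, 3194 were higher and 77 lower. With GC adjustment 11005 genes were called, of which 6662 had the same direction as before (3243 higher, 3419 lower) and 1172 the opposite one. The same direction and at least a 2-fold change in both fits was found for 1455 higher and 1909 lower genes. Of the pseudogenes and small RNAs among the largest falls, RPL13P8, CDC42P2 and RNU6-26P share sequence with related genes and are uncertain, and CCDC168 had 2 counts against 126 (ratio 71.0 in favour of vehicle, exact 95% interval 19.2 to 592). GPER1 differed by 0.93 ± 0.39 (adjusted p = 0.0616), and with GC adjustment by -0.53 ± 0.15 (adjusted p = 0.0126), and it was called at 1.69 without vehicle replicate 2, so its direction was not settled.

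Estradiol against vehicle asked what the hormone did in cells without introduced ERβ. No common shift of classical estrogen receptor target genes was detected, with 8 of 15 above vehicle and a camera adjusted p of 0.716. Of the 15, 0 were called, but so were 0 of all 18495 genes, so that count is not particular to this list. Adjusted over the list alone it was also 0. In simulation only 10% of genes changed by 1 log2 unit were recovered in this comparison, so small shifts could be missed. CTSD, a lysosomal protease gene often induced by ERα, was at 72.1 ± 6.92 CPM with estradiol and 25.9 ± 21.7 with vehicle (log2 fold change 1.48 ± 0.51, adjusted p = 0.198; GC-adjusted 0.62 ± 0.18), and RARA was at 14.1 ± 1.55 and 6.73 ± 3.95 CPM. GPER1 was at 29.6 ± 1.12 CPM against 10.2 ± 6.25 (1.53 ± 0.39, adjusted p = 0.198). After GC adjustment it stood at 0.84 ± 0.14 with an adjusted p of 0.04998, among 16 genes then called higher beside 101 called lower. These GC-adjusted calls fell to 0 without vehicle replicate 1 or any 1 of the estradiol or G1 libraries, and numbered 1019 without vehicle replicate 2 and 3921 and 3884 without ERβ plus ICI replicate 2 or 3.

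Of the gene lists, 6 were called with estradiol. The G1/S list was higher (camera adjusted p = 0.00252; adjusted p = 0.478 with an estimated correlation), with 18 of 20 members above vehicle, none called singly, and a GC-adjusted p of 7.68e-05. Its median GC content is 49.8%. The replicative helicase genes MCM2 and MCM5 were at 509 ± 2.31 against 277 ± 77.7 CPM and at 231 ± 9.05 against 111 ± 52.7 CPM. Tubulin genes, at a median GC content of 57.8%, were higher in 11 of 11 members (camera adjusted p = 0.00252; adjusted p = 0.588 with an estimated correlation), with TUBB6 at 27.7 ± 1.53 against 13.5 ± 3.90 CPM and TUBB4B at 817 ± 32.1 against 411 ± 188 CPM, but not after GC adjustment (adjusted p = 0.237). Ribosomal protein genes were higher (adjusted p = 0.00975; adjusted p = 0.478 with an estimated correlation; GC-adjusted p = 0.0141), with RPLP1 at 411 ± 4.65 against 180 ± 113 CPM. Mitochondrially encoded genes were lower in 12 of 13 members (adjusted p = 0.0287; adjusted p = 0.564 with an estimated correlation; GC-adjusted p = 0.0245), at a median of -0.13, with MT-ND2 at 1546 ± 193 against 1791 ± 15.6 CPM. Wnt targets and colon differentiation genes were higher (both adjusted p = 0.0266; adjusted p = 0.652 and adjusted p = 0.564 with an estimated correlation), and GC adjustment ended both calls (0.248 and 0.0890). APCDD1, a Wnt antagonist, was at 81.2 ± 3.06 against 42.7 ± 12.8 CPM, SP5 at 73.2 ± 6.87 against 39.0 ± 13.0 (0.91 ± 0.26, and GC-adjusted -0.35 ± 0.21, in the opposite direction), KRT8 at 2360 ± 37.1 against 1289 ± 397 and CDX2 at 8.84 ± 0.57 against 4.82 ± 0.35. Aryl hydrocarbon receptor targets were called higher only with GC adjustment (camera adjusted p = 0.0864 without it and 0.016 with it). With an estimated correlation, used only without offsets, their camera adjusted p was 0.478.

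No gene passed the threshold for estradiol against vehicle in edgeR or limma-voom, while 3928 of 18495 had an unadjusted p under 0.05. DESeq2, with no count filter beforehand, called 756 of 31078 genes tested, and limma on the deposited FPKM 34 of 20017. In the simulation of this comparison without a GC trend, DESeq2 called 32 unchanged genes and edgeR 6. Adjusted over the list alone, 3 aryl hydrocarbon receptor targets, 2 integrated stress response genes, 2 colon differentiation genes and 1 epithelial-mesenchymal gene were higher, 1 YAP/TEAD target and 1 NF-κB gene lower, and TGF-β targets gave 2 in each direction, with 0 in every other list. The vehicle libraries were far apart, and 2245 genes were called without replicate 2 (1954 higher) and 0 without replicate 1. Without ERβ plus ICI replicate 2, a library of a group not compared here, 1158 of 19202 genes tested were called. Genes of 55.7 to 74.5% GC had a median log2 fold change of 0.63 with estradiol and those of 23.5 to 42.2% GC one of -0.42.

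G1 against vehicle asked what a GPER1 agonist did in the same cells. Cholesterol synthesis genes were higher as a list (camera adjusted p = 0.00517; adjusted p = 0.305 with an estimated correlation), with 19 of 21 members above vehicle, a median of 0.35 and a GC-adjusted p of 6.66e-07. The 7-dehydrocholesterol reductase gene DHCR7 was at 216 ± 1.30 CPM against 121 ± 37.6. The list's median GC content, 48.6%, is close to that of all genes. CDH1 was at 54.9 ± 2.12 CPM against 24.3 ± 1.72 (1.18 ± 0.20, adjusted p = 0.193; GC-adjusted 1.25 ± 0.09, adjusted p = 0.00434), and fibronectin (FN1) at 3.58 ± 0.56 against 7.38 ± 0.19 CPM.

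Further lists were higher with G1. Hypoxia and glycolysis genes (camera adjusted p = 0.0232; adjusted p = 0.305 with an estimated correlation; GC-adjusted p = 0.0016) included CA9 at 47.7 ± 5.12 against 24.4 ± 7.21 CPM. Colon differentiation genes were above vehicle in 11 of 11 members (adjusted p = 0.00715; adjusted p = 0.305 with an estimated correlation; GC-adjusted p = 0.0439), with TFF3 at 44.2 ± 3.72 against 15.9 ± 9.89 CPM. For aryl hydrocarbon receptor targets the adjusted p was 0.0431 (adjusted p = 0.305 with an estimated correlation; GC-adjusted p = 0.0181), with the aldehyde dehydrogenase gene ALDH3A1 at 17.0 ± 1.77 against 5.70 ± 3.11 CPM. The calls of integrated stress response genes (adjusted p = 0.0239), ribosomal protein genes (0.0224) and immediate early genes (0.0457) were lost with GC adjustment (0.120, 0.0682 and 0.277) and with an estimated correlation (adjusted p = 0.305, adjusted p = 0.305 and adjusted p = 0.435). With GC adjustment the medians of the stress response and immediate early lists fell from 0.35 to 0.086 and from 0.421 to 0.092. That of the ribosomal protein genes changed little, from 0.237 to 0.205. With fry, run without offsets, the stress response list kept its call (adjusted p = 0.0299). The ribosomal protein and immediate early lists did not (fry adjusted p = 0.0587 and 0.125). TRIB3 was at 65.3 ± 1.81 against 34 ± 6.92 CPM, PHGDH, of serine synthesis, at 53.4 ± 3.05 against 29.4 ± 5.6 and ATF3 at 3.03 ± 0.15 against 1.44 ± 0.41. Estrogen receptor targets had a camera adjusted p of 0.811 and markers of other cell types one of 0.203. In each 0 members were called, as in every list of this comparison.

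No gene passed the threshold for G1 against vehicle in edgeR or limma-voom, 2445 of 18495 had an unadjusted p under 0.05, DESeq2 called 117 and limma on FPKM 24. Adjusted over the list alone, 3 integrated stress response genes, 1 aryl hydrocarbon receptor target and 1 cholesterol synthesis gene were higher, 1 TGF-β target lower, and epithelial-mesenchymal genes gave 3 higher and 2 lower, with 0 in every other list. Without vehicle replicate 2, 1553 genes were called (1438 higher) and 0 lists, and GC adjustment gave 155 higher and 237 lower genes. These GC-adjusted calls fell to 0 without vehicle replicate 1 or either G1 library and to 11 without either estradiol library, and numbered 794 without vehicle replicate 2 and 2819 and 2783 without ERβ plus ICI replicate 2 or 3.

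Estradiol and G1 were compared directly, at 10 nM and 1 µM, so that dose differed together with compound. CDH1 was at 16.1 ± 0.68 CPM with estradiol and 54.9 ± 2.12 with G1 (-1.77 ± 0.20, adjusted p = 0.0437). The membrane-binding annexin gene ANXA6 was at 4.63 ± 1.20 and 29.6 ± 1.22 CPM (-2.68 ± 0.31), the secreted growth factor carrier FGFBP1 at 0.80 ± 0.12 and 4.59 ± 0.40 (-2.51 ± 0.28) and the calpain gene CAPN6 at 2.83 ± 0.27 and 12.8 ± 1.19 (-2.17 ± 0.22). ALDH1A2, which makes retinoic acid, was at 2.39 ± 0.30 with estradiol and 0.33 ± 0.08 with G1 (2.83 ± 0.31). These 5, all at an adjusted p of 0.0437, were the genes called of 18495, 1 higher and 4 lower with estradiol, and all 5 stayed called after GC adjustment, among 219. Those 219 fell to between 2 and 9 without 1 of the estradiol or G1 libraries and numbered 855 and 837 without ERβ plus ICI replicate 2 or 3. The log2 fold change correlated with GC content at 0.22 across genes, less than for the comparisons with vehicle.

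**Figure D3:**
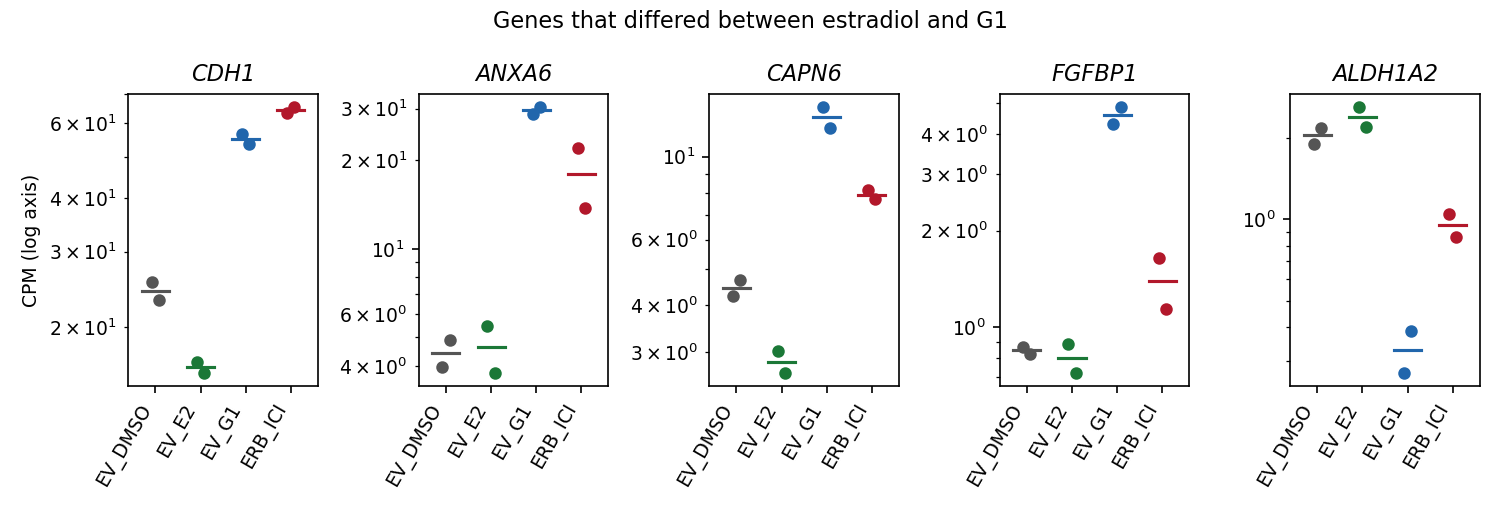
Expression of the 5 genes called between estradiol and G1, in CPM on a log axis, with 1 point per library and a bar at the mean of each group of 2 libraries (EV, empty vector; ERB, ERβ; E2, estradiol). CDH1 averaged 24.3 CPM with vehicle, 16.1 with estradiol, 54.9 with G1 and 64.2 with ERβ plus ICI.

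Cholesterol synthesis genes were lower with estradiol than with G1 (camera adjusted p = 4.19e-05; adjusted p = 0.243 with an estimated correlation; GC-adjusted p = 3.37e-08), in 17 of 21 members and at a median of -0.26. INSIG1 was at 25.8 ± 3.71 against 56.2 ± 3.21 CPM. G1/S genes were higher with estradiol in 20 of 20 members, at a median of 0.25 (camera adjusted p = 4.19e-05; adjusted p = 0.220 with an estimated correlation; GC-adjusted p = 2e-05), with cyclin E1 (CCNE1) at 10.7 ± 0.28 against 7.43 ± 0.21 CPM and TYMS at 280 ± 22.1 against 221 ± 8.85. Tubulin and Wnt target genes were higher too (both adjusted p = 0.0142; both adjusted p = 0.853 with an estimated correlation), and GC adjustment kept the tubulin call (0.0234) and ended that of the Wnt targets (0.0575). TUBB6 was at 27.7 ± 1.53 against 14.1 ± 0.65 CPM, TUBA1A at 13.9 ± 1.16 against 25.2 ± 5.59, and the Wnt feedback gene NKD1 at 1984 ± 61.7 against 1543 ± 3.36. Immediate early and MAPK feedback genes were called lower with estradiol only with GC adjustment (camera adjusted p = 0.0704 without it and 0.00719 with it). With an estimated correlation, used only without offsets, their camera adjusted p was 0.853. Estrogen receptor targets had an adjusted p of 0.996 and markers of other cell types one of 0.644. Adjusted over the list alone, 2 cholesterol synthesis genes and 1 each of the YAP/TEAD, p53 and other-cell-type lists were lower, 2 epithelial-mesenchymal genes higher and 1 lower, and 1 TGF-β target in each direction. The 5 calls were lost without any 1 of the estradiol or G1 libraries, without ERβ plus ICI replicate 2 and when genes needed 1 CPM in 2 libraries, and a fit of these 4 libraries alone called 2701 genes. DESeq2, with no count filter beforehand, called 75 of 31078 genes tested. The 5 genes called by limma-voom were all lower with estradiol, so ALDH1A2 was not among them.

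The comparisons against vehicle share its libraries. No gene was called in the same direction in any pair of them, since none was called for estradiol or G1. Fold changes correlated across genes at 0.74 for estradiol and G1, 0.68 for estradiol and ERβ plus ICI and 0.66 for G1 and ERβ plus ICI. Simulated unchanged groups that shared simulated vehicle libraries gave 0.51 in each pair. The covariances were 0.307, 0.767 and 0.668 against a simulated 0.072. With GC adjustment the correlations were 0.64, 0.47 and 0.51 against simulated values of 0.52, 0.51 and 0.51, and the covariances 0.180, 0.309 and 0.323 against 0.043. The overlaps were then 48 genes for estradiol and G1 (6 higher and 42 lower, 0.1 and 1.3 for independent lists), 99 for estradiol and ERβ plus ICI (10 and 89, against 4.8 and 29.8) and 285 for G1 and ERβ plus ICI (107 and 178, against 46.5 and 69.9). The simulations drew all 8 libraries, vehicle included, from the same mean per gene, with no GC trend and no offsets fitted. The real vehicle libraries, which differed in that trend, did not enter them. What sharing those libraries gives alone is therefore not bounded by the simulated values, nor by their overlap of 0. At an unadjusted p under 0.05 the overlaps with GC adjustment were 2206, 2972 and 2661 genes in that order, against simulated means of 198, 198 and 200.1. With 2 vehicle libraries a split would leave 1 in each part and was not made, and part of these correlations and overlaps may come from sharing them.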

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

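All fits with GC and length offsets, those of the 6 empty-vector libraries without the block, and leaving out libraries of groups not compared were chosen only after the results were seen; the other alternatives were fixed before. Called genes for estradiol against vehicle, 0 in the reported fit, were 756 with DESeq2, 34 with FPKM and a pseudocount of 1, 39 with 0.1, 64 without the FPKM filter, 2408 without a count filter, 117 with GC and length offsets, 1570 with the 6 empty-vector libraries and 4009 with both. For G1 against vehicle, also 0, they were 117, 24, 30, 63, 1134, 392, 0 and 2920 in that order. For estradiol against G1, 5 in the reported fit, they were 75, 28, 31, 33, 197, 219, 0 and 880, with 2701 in the 4 libraries compared and 0 with a filter of 1 CPM. The genes tested differed too, with 18495 in the reported fit, 31078 with DESeq2 and 20017 with filtered FPKM. The cause was not tested.

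Same-direction overlaps, 0 in the reported fit, were, without a filter, with DESeq2, with FPKM at pseudocounts of 1 and 0.1 and unfiltered, and with offsets, 758, 30, 12, 18, 34 and 48 for estradiol and G1, 2191, 709, 24, 29, 50 and 99 for estradiol and ERβ plus ICI, and 1007, 95, 19, 25, 45 and 285 for G1 and ERβ plus ICI. For estradiol and G1 the 6 libraries with offsets gave 1666. Called lists numbered 6 for estradiol, 7 for G1, 5 for ERβ plus ICI and 4 for estradiol against G1. They were 0 in each with an estimated correlation, 0, 2, 10 and 0 with fry, and 4 for G1 and 8 for ERβ plus ICI with offsets at the preset correlation. For G1, fry called hypoxia and glycolysis genes and integrated stress response genes (both fry adjusted p = 0.0299). For ERβ plus ICI its 10 included the 5 that camera called, with stress response genes at 6.13e-06 and G2/M genes at 7.48e-04.

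Without 1 library at a time, called genes ranged from 0 to 2245 for estradiol (0 to 3921 with offsets), 0 to 1553 for G1 (0 to 2819), 9265 to 13224 for ERβ plus ICI (9205 to 11626) and 0 to 10 for estradiol against G1 (2 to 855). A lone library of a group was assumed to vary like the other groups. Called lists ranged from 3 to 7 (3 to 5), 0 to 8 (3 to 6), 5 to 7 (7 to 9) and 3 to 4 (3 to 4). Overlaps ranged from 0 to 1340 for estradiol and G1 (0 to 1600), 0 to 2146 for estradiol and ERβ plus ICI (0 to 2786) and 0 to 1484 for G1 and ERβ plus ICI (0 to 1973).

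With the replicate number as a block in the 6 empty-vector libraries, 0 genes were called in each comparison, and with the block and offsets 4457 for estradiol, 3388 for G1 and 901 for estradiol against G1, with an overlap of 2064 for estradiol and G1. The differences of library 1 minus library 2 within a group were correlated between groups across genes. The correlation was 0.107 for vehicle and estradiol, 0.223 for vehicle and G1 and 0.063 for estradiol and G1, and 2 numbers do not show pairing. The block was not fitted for ERβ plus ICI, which shares 1 replicate number with vehicle.

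A direction was taken as turned only where at least 1 of the fits called the result. Directions turned with GC and length offsets in ERβ plus ICI against vehicle for GPER1 (-0.53), Wnt/beta-catenin target genes (adjusted p = 0.0356) and tubulin genes (adjusted p = 0.0193). Both list calls are from camera at the preset correlation. With an estimated correlation, used only without offsets, camera gave both lists an adjusted p of 0.976. Without 1 library, GPER1 lay at -0.69 to -0.33 with offsets and 0.40 to 1.69 without them, the Wnt adjusted p at 0.0183 to 0.0468 and 0.76 to 0.973, and the tubulin adjusted p at 0.00663 to 0.0544 and 0.263 to 0.99. SP5 with estradiol lay at -0.71 to 0.07 with offsets and 0.60 to 1.23 without them; it was called without vehicle replicate 2 in both, in opposite directions. The cause was not tested. Upper-quartile scaling moved the median log2 fold change of all genes between ERβ plus ICI and vehicle from 0.04 to 0.16 and the share of higher genes among the called from 50.5% to 55.1%. Over all alternatives, 4205 values of the genes chosen for naming stayed on their side of the threshold, 464 came to pass it and 105 no longer did, and for gene lists these were 2481, 85 and 167.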

Other observations

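The tests with GC and length offsets, the slope between the vehicle libraries, the comparison with random gene sets and the use of each test for an explanation were chosen only after the results were seen, while the fits without offsets and those without 1 library of the groups compared were fixed before.

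With GC and length offsets, 117 genes were called between estradiol and vehicle, 392 between G1 and vehicle and 219 between estradiol and G1, and the genes named here were chosen after their values were seen. ALDH1A2, which makes retinoic acid, was at 0.33 ± 0.08 CPM with G1 and 2.04 ± 0.20 with vehicle (GC-adjusted log2 fold change -2.65 ± 0.27, adjusted p = 0.0102). CRABP1, a retinoic acid carrier gene, was at 0.69 ± 0.12 CPM with estradiol and 2.81 ± 0.36 with G1 (-2.16 ± 0.25, adjusted p = 0.00744). Also higher with G1 than with estradiol were the cholesterol exporter gene ABCA1 at 2.66 ± 0.27 against 0.34 ± 0.05 CPM (-2.91 ± 0.33, adjusted p = 0.00652), the apolipoprotein gene APOH at 6.27 ± 0.11 against 1.5 ± 0.27 CPM (-2.01 ± 0.18, adjusted p = 0.00261) and the sterol importer gene NPC1L1 at 3.92 ± 0.39 against 1.16 ± 0.13 CPM (-1.88 ± 0.26, adjusted p = 0.0149).

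The mesenchymal gene VIM was at 710 ± 37.9 CPM with estradiol and 326 ± 0.58 with G1 (1.13 ± 0.13, adjusted p = 0.00652), and the secreted chaperone gene CLU at 21.9 ± 2.1 and 6.92 ± 0.51 CPM (1.61 ± 0.13, adjusted p = 0.00236). TAGLN, an actin-binding TGF-β target, was at 84.4 ± 4.05 CPM with estradiol and 35.2 ± 13.1 with vehicle (0.83 ± 0.11, adjusted p = 0.0358), and the cell cycle inhibitor gene CDKN2B at 6.51 ± 0.07 and 14.4 ± 0.21 CPM (-0.95 ± 0.12, adjusted p = 0.0358). Without the offsets none of these genes was called in the comparison given for it here. With the offsets, 0 genes were called between G1 and vehicle without vehicle replicate 1 or either G1 library, and 0 between estradiol and vehicle without vehicle replicate 1 or any 1 of the estradiol or G1 libraries, so that the calls of ALDH1A2, TAGLN and CDKN2B were lost there. Between estradiol and G1 they left 2 to 9 genes without 1 of the libraries compared.

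Between ERβ plus ICI and vehicle, 11656 of 18495 genes were called without the offsets. With and without the offsets, 6662 genes were called in the same direction and 1172 in opposite ones. The 6662 argue against a GC and length trend of the fitted form as the whole cause. Simulated unchanged genes gave 10234 calls without the offsets and 9 with them. They carried the fitted trend itself, so they do not show how well the offsets remove the real one. Such a trend may be a large part of the cause of the calls without offsets. In simulation it gave 10234 calls among unchanged genes. The vehicle libraries, given the same treatment, also differed by 0.516 log2 units per 10 percentage points of GC. The fitted trend may itself hold a response that follows GC content, which these values do not separate. Whether ICI or the ERβ transduction lies behind the remaining change cannot be told apart, because 0 libraries carried ERβ without ICI.

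The rise of integrated stress response genes in the ERβ plus ICI libraries had a median of 2.48 with GC and length offsets, which argues against that trend. It had a median of at least 2.84 without any 1 library of the groups compared (adjusted p from 4.12e-10 to 5.74e-07 at the preset correlation), which argues against 1 aberrant library. With an estimated correlation the list had an adjusted p = 0.0565 over all libraries. Effects of the compound and of the transduction, which the design does not separate, and a difference in culture conditions stay open and were not tested.

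The genes that differed between estradiol and G1 all stayed called with GC and length offsets (5 of 5), which argues against the GC trend for these genes. The smallest difference without any 1 library of the groups compared was 1.72 log2 units, for CDH1 without estradiol replicate 2, where none passed the threshold with 1 library left in a group (smallest adjusted p 0.286). Because these genes were called for the closeness of the libraries within each group, that difference does not decide on 1 aberrant library, which stays open. Of 219 genes called with the offsets, 148 (67.6%) lay on the side in ERβ plus ICI against vehicle on which they lay in G1 against estradiol. Random sets matched on expression and on direction had a median of 47.5%, and 0 of 10000 reached as many. The sets were drawn gene by gene, as if genes varied independently, so that count does not measure chance agreement of genes that vary together. These comparisons share no library, but the ERβ plus ICI libraries also received a compound, together with the transduction. The agreement thus does not tell variation of the same genes between cultures from a shared effect of the treatments, and both stay open.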
